A study of Caenorhabditis elegans with 2 samples.

How the data were processed

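The series holds chromatin immunoprecipitation followed by sequencing (ChIP-seq) from whole Caenorhabditis elegans worms in which the arid-1 gene carries a tag with EGFP and 3xFLAG, inserted at its own locus by CRISPR. Per the labels, worms were synchronised by starving newly hatched larvae after bleaching, collected as L4 larvae at 47 hours, and the tagged protein was precipitated with an antibody against GFP from chromatin broken by sonication. There are 2 samples, which the labels number as biological replicates 1 and 2 and tie to different biosamples, and 1 group. No comparison between groups follows from this design, and values of a control library were not used here.

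The 8 deposited lists that were used give peaks on the ce11 build, per the labels. Each replicate has a ranked list and a thresholded list of its own, and the series has 2 ranked lists and 2 thresholded lists made from both replicates' alignments, per the file notes among the deposited files. The aligner, the peak caller and their versions are not given in the sources used here. The deposited lists give a signal per peak, which is the authors' own value from their peak caller, and the position of the peak's summit. Signal is used here to describe, rank and filter peaks within a list, and to compare the replicates' ranked lists at the same peaks. The scaling between lists is not given in the sources used here, so the SD of signal over the replicates and their log2 ratio may include a difference in scale. The authors' ranked lists also give the −log10 of the irreproducible discovery rate (IDR), a measure of how well a peak's rank repeats between 2 peak sets. Every peak of the conservative thresholded list was found in 1 of the ranked lists of the series with a −log10 IDR of at least 2, which is an IDR of 0.01. Of the intervals that this ranked list gives for its first and second component, 48.2% and 46.2% are also intervals of the ranked lists of replicate 1 and replicate 2. For the other ranked list of the series these shares are 4.16% and 0.00484%. The conservative list was therefore taken, as planned, as the main peak set, and the other thresholded list of the series as an alternative. The ranked lists of the series also carry 4 columns with the signal of their components, without a header, which were not used. No read count is given in the lists, so the depth of each library is unknown, and no limit of detection was computed.

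Peak positions were compared with the WBcel235 assembly, the sequence of ce11, with gene models of Ensembl release 115. No peak of the conservative list ends beyond the length of its chromosome. Names of genes on the mitochondrial genome, and others without a name in that annotation, were taken from the RefSeq annotation of the same assembly. A peak was placed by its summit. Summits were sorted into 7 classes in this order: promoter (within 500 bp of the annotated 5' end of a protein-coding gene), 5' UTR, coding exon, 3' UTR, intron, non-coding gene and intergenic. Many worm genes are trans-spliced, so an annotated 5' end is not always where transcription starts. Shares per class, and the number of peaks that overlap a gene of each of 7 non-coding classes, were tested against 1000 circular shifts of the peaks along their chromosomes (2-sided). The share of a replicate's peaks that overlap a peak of the other replicate by at least 1 bp was tested in the same way (1-sided). The smallest p that 1000 shifts can give is 0.001. Shares on the X chromosome and in the middle of the autosomes were tested with exact binomial tests against the share of sequence length and of protein-coding 5' ends.

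A gene was counted as holding a summit when a summit of the conservative list lay within 500 bp of its 5' end. For 26 gene lists, fixed by gene symbol before the data were examined, the share of such genes was compared with that among all other protein-coding genes of the nuclear chromosomes by Fisher's exact test (2-sided). Log2 signal was compared between promoter peaks and other peaks by a permutation test with 100000 resamples. The signal of each list's promoter peaks was compared with 10000 random draws of as many promoter peaks. The GC share of 201 bp around each summit was compared with windows centred 1000 bp to either side by a sign-flip permutation test with 100000 resamples. The presence of 7 fixed motifs, and of every 6-mer counted with its reverse complement, was compared between summit and flank windows by Fisher's exact test. All p-values were adjusted by the Benjamini-Hochberg method within the classes, lists, motifs or 6-mers of a test. Peaks are not replicates of an experiment, and these p-values describe the peaks of these lists. Intervals for shares and for the odds ratios of gene lists are exact intervals at the 95% level. Those for odds ratios under Other observations are approximate and symmetric on the log scale. All of them cover counting error only.

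Genes were named by a rule fixed before the data were examined. It takes arid-1 and 4 further genes listed for the SIN-3 complex. It also takes the genes at the 25 peaks of highest signal that overlap a peak of both replicates' own lists. Up to 4 members of each gene list that held summits more often are named, and 2 genes of each non-coding class that passed its test. Since most of these 25 peaks proved to be mitochondrial, the 25 highest nuclear peaks were added after the data were seen. A value for each replicate at a conservative peak is the highest signal among the overlapping peaks of that replicate's ranked list, given as mean and SD over both replicates.

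Alternatives fixed before the data were examined were the other thresholded list, each replicate's own list in place of the conservative list, the higher-signal part of the list, other promoter windows, 5' ends of every transcript, assignment to the nearest gene, circular shifts in place of Fisher's test, a background of genes with a symbol, other sequence windows, and other rules for overlap. Alternatives chosen after seeing the data were the nuclear chromosomes alone, the list without peaks at tRNA, snoRNA or snRNA genes, the list with ranked peaks that the conservative list lacks, and sequence windows matched on GC. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

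The procedures were tested on simulated data. With 20 sets of 2330 randomly placed peaks and 19973 genes, 0 of 520 random lists were called, and 1 of the fixed lists was called. Of 100 lists with 20 members given a peak, 100 were recovered, and 5 lists without planted peaks were called beside them. Members of these lists were scattered genes, and the planted share exceeded that of every list called below except ribosomal proteins. Recovery of weaker or clustered lists was therefore not tested. With 50 peaks planted on tRNA genes, 55 peaks lay at tRNA genes, and 1 other non-coding class was also called. A planted 6-mer ranked first among 2080.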

Results

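ARID-1 is a protein with an AT-rich interaction domain. The gene list used here for the SIN-3 histone deacetylase complex holds arid-1, sin-3, hda-1, mrg-1 and athp-1. Whether their proteins share a single complex was not examined. The binding of ARID-1 across the genome was measured by ChIP-seq in whole L4 larvae, with 2 biological replicates of a single group. Positions are on the ce11 build. The question the design addresses is where in the genome tagged ARID-1 is found at this stage. The conservative list of the series holds 2330 peaks, 2306 of them on the nuclear chromosomes and 24 on the mitochondrial genome. The nuclear peaks cover 0.595% of the nuclear genome, and the median peak is 270 bp wide. The replicates' own thresholded lists hold 1230 and 1257 peaks. The number of reads behind each list is unknown.

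Most peaks of either replicate's own list lay on a peak of the other's. Of the peaks of replicate 1, 65.5% (exact 95% interval 62.8 to 68.2) overlapped a peak of replicate 2, and 63.8% (61.1 to 66.5) of the peaks of replicate 2 overlapped a peak of replicate 1. Shifted lists overlapped by 2.62% and 2.48% on average and by at most 3.50%, and the 1-sided permutation p was 0.001 in both directions, the smallest that 1000 shifts can give. The 424 peaks of replicate 1 without a partner had a lower median signal (43.2) than the 806 with a partner (60.3), and 370 of them lay on a peak of the other replicate's ranked list. Of the conservative peaks, 797 overlapped a peak in both replicates' own lists and 896 in neither, with a median signal of 123 and 60.8. Signal in the replicates' ranked lists could be compared at 2261 nuclear conservative peaks, where Pearson's r of log2 signal was 0.739 and Spearman's rho 0.603. The conservative peaks were selected for ranks that repeat between peak sets. Over all 19173 nuclear ranked peaks that the replicates share, r was 0.550 and rho 0.423, with an SD of the log2 ratio of 0.73. These correlations are across peaks, which are not independent replicates. At the conservative peaks, the log2 ratio of replicate 2 to replicate 1 had a median of 0.11 and an SD of 0.43. The median may include a difference in scale between the lists.

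**Figure D1:**
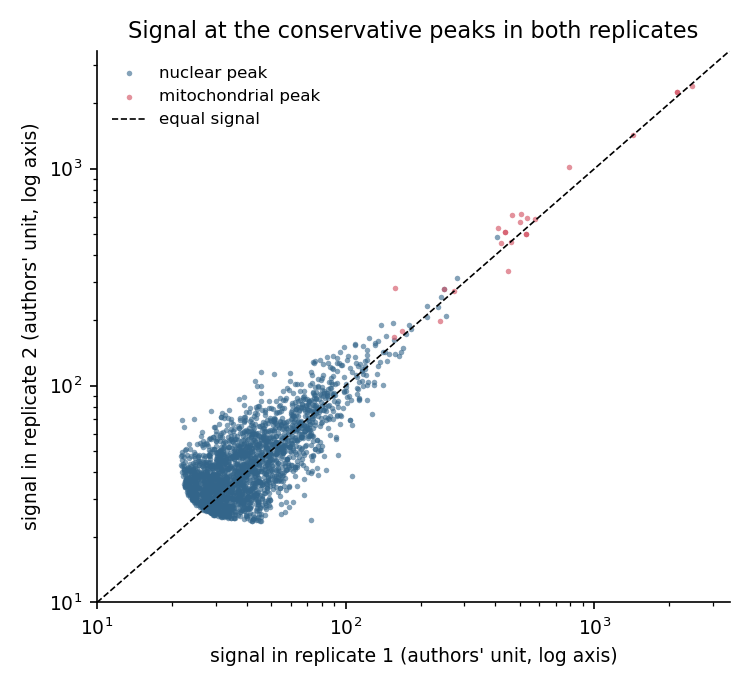
Signal in replicate 1 (x axis) and replicate 2 (y axis), in the authors' unit on log axes, at 2285 conservative peaks with a ranked peak in both replicates. Each point is a peak, mitochondrial peaks are red, and the dashed line marks equal signal. Points follow the line, with a wider spread at low signal.

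Summits lay more often than shifted summits near 5' ends of protein-coding genes and in non-coding genes, and less often in coding exons and introns. Of the 2330 summits, 959 (41.2%) lay within 500 bp of an annotated protein-coding 5' end, against 19.04% of shifted summits, a 2.16-fold difference, and with 250 bp windows 27.04% against 9.93%. In the replicates' own lists the promoter share was 41.0% ± 0.8 (SD, n = 2). Coding exons held 5.11% of summits against 19.2% after shifts, and introns 19.7% against 29.7%. The share of coding exons was 3.38% ± 0.17 (SD, n = 2) in the replicates' own lists and 2.23% among the 1165 peaks of higher signal. Non-coding genes outside these classes held 8.63% against 3.52%, a difference lost without peaks at tRNA, snoRNA or snRNA genes (3.67% against 3.52%, adjusted permutation p = 0.915). The adjusted permutation p was 0.0014 for each of these classes, from the smallest p that 1000 shifts can give. The 5' UTR share of 0.858% and the 3' UTR share of 3.13% did not pass the test against shifted summits (adjusted permutation p = 0.263 for both). The 3' UTR share passed in the other list of the series (3.48%, adjusted permutation p = 0.0315) and without peaks at tRNA, snoRNA or snRNA genes (3.77%, adjusted permutation p = 0.0105), and turned among the 1165 peaks of higher signal (1.80%, adjusted permutation p = 0.0571). Intergenic sequence held 21.4% of summits against 25.1% (adjusted permutation p = 0.0014). This difference was lost without peaks at tRNA, snoRNA or snRNA genes (24.5%, adjusted permutation p = 0.961) and with 95 ranked peaks added that pass the IDR threshold and are absent from the conservative list (24.2%, adjusted permutation p = 0.377). Both alternatives were chosen after seeing the data. The difference turned with 250 bp promoter windows (29.2% against 28.2%, adjusted permutation p = 0.334). Promoter summits lay upstream of the nearest 5' end in 77.0% of cases, with a median position 146 bp upstream.

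**Figure D2:**
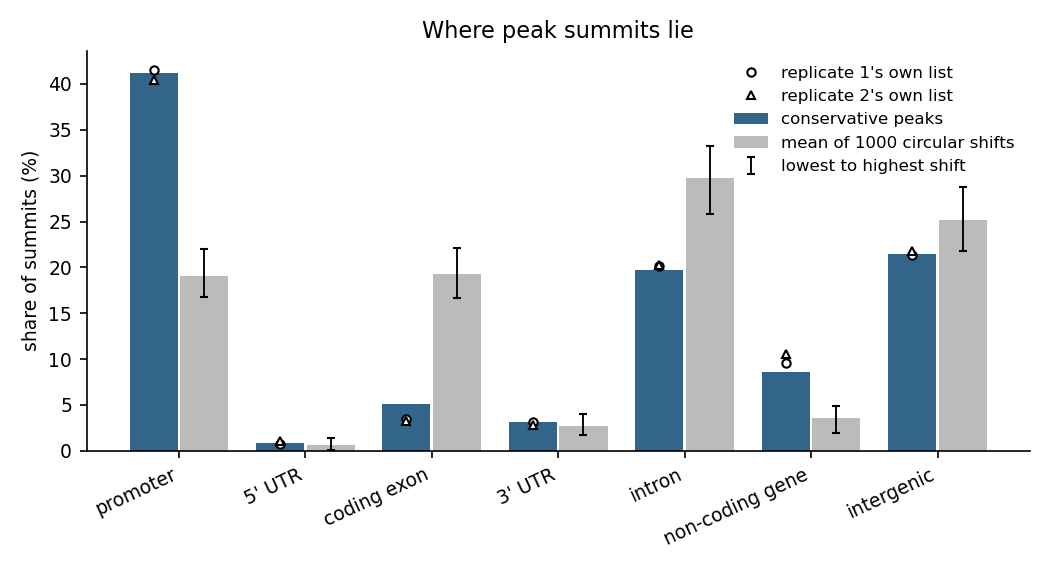
Share of summits in each annotation class (y axis, percent) for the conservative peaks (blue bars) and the mean of 1000 circular shifts (grey bars, with whiskers from the lowest to the highest shift). Open circles and triangles show replicates 1 and 2. Promoters held 41.2% of summits and coding exons 5.11%.

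Several of the highest nuclear peaks lay at genes of the cytosolic ribosome. The highest lay on chromosome III at 3867464 to 3867684, with its summit 285 bp upstream of rpl-3, a protein of the large ribosomal subunit, and a signal of 444 ± 56.0 (SD, n = 2) in the replicates. The next lay at chromosome III 10759125 to 10759359, 63 bp upstream of tasp-1 (297 ± 24.1, n = 2). It was followed by a peak on chromosome IV, 654831 to 655030, in the region shared by rpl-15 and K11H12.8 (263 ± 21.3, n = 2), and by peaks upstream of rpl-35 (249 ± 11.6, n = 2), cdc-48.1 (233 ± 3.9, n = 2), and the divergent pair rpl-20 and Y17G9B.5 (223 ± 14.3, n = 2). CDC-48.1 is an AAA ATPase of protein degradation. Some of the highest peaks had no protein-coding 5' end in the window. These included a peak in an intron of pxn-1 over the snoRNA gene ZK994.7 (chromosome V, 8500444 to 8500649), with a signal of 231 ± 32.1 (n = 2). Among the 25 highest nuclear peaks, those added after the data were seen also include the promoters of rps-1, hsr-9 and rps-19, cox-5B, rpl-7A and set-21, wip-1, cox-5A, Y55F3AR.2 and cct-8, mtcu-2 and eel-1.

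The mitochondrial genome carried 18 of the 25 peaks that the rule for named genes takes. Its 24 peaks cover 54.9% of its sequence and have a median signal of 928, against 75.97 for nuclear peaks. The highest lay at 13046 to 13381, over the end of ND5 and a neighbouring tRNA gene (2443 ± 39.6, n = 2), and another at 4302 to 5405 over CYTB and 4 tRNA genes (2203 ± 77.0, n = 2). Further windows were those of ATP6, ND1, ND3, ND4, COX2 and COX3, all subunits of respiratory complexes. The windows of 2 more genes, at 3389 to 4269 and 7827 to 9428, were also among them. The matching of annotations used here gave these 2 genes no symbol, which does not mean that they lack one. The share of reads from mitochondrial DNA cannot be had from peak lists.

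Of the 5 genes listed here for the SIN-3 complex itself, 1 held a summit at its 5' end. That gene was mrg-1, which encodes a chromodomain protein. Its summit lay 242 bp from its 5' end on chromosome III (12874842 to 12874926), with a signal of 70.9 ± 21.3 (SD, n = 2). This summit lies nearer to the 5' end of another protein-coding gene. With each summit given to its nearest gene, mrg-1 thus no longer held one. No summit of the conservative list lay within 500 bp of the 5' end of arid-1, sin-3, hda-1 or athp-1. The nearest summits lay 59407, 5461, 56638 and 4059 bp away. Short of the IDR threshold, 2 ranked peaks lay in the window of sin-3 (best −log10 IDR 0.70) and 2 in that of athp-1 (0.91). Windows of arid-1 and hda-1 held 0. The gene list of the complex did not pass the threshold (odds ratio 4.16, 95% interval 0.0843 to 42.04, adjusted p = 0.295, Fisher's exact test with Benjamini-Hochberg adjustment). With 5 members its interval is wide.

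Among the 26 gene lists, ribosomal protein genes had the highest share with a summit at the 5' end. A summit lay within 500 bp of the 5' end of 1134 of 19973 protein-coding genes (5.68%). Of the lists, 10 held summits more often than other genes and 4 less often. Of nuclear promoter peaks, 23.7% had the 5' ends of 2 or more genes in the window. Fisher's test counts genes that share a summit as independent, which they are not. Ribosomal protein genes had summits at 51 of 79 members (64.6%; odds ratio 31.6, 95% interval 19.5 to 52.3; adjusted p = 1.05e-42 by Fisher's exact test). In the replicates' own lists 41.1% ± 0.9 (SD, n = 2) of them held a summit, and with 250 bp windows 21.5% did. The highest members were rpl-3, rpl-15, rpl-35 and rpl-20. Other genes held summits in 2.87% and 2.90% of cases in the lists of replicates 1 and 2. With 250 bp windows they did so in 3.45%, against 5.44% in the main setting. A list's shares under different settings are thus not directly comparable. The odds ratio of ribosomal protein genes, which sets them against other genes, was also smaller with 250 bp windows (7.67, 95% interval 4.18 to 13.4). The lower share of these genes with 250 bp windows thus does not come from the lower share of other genes alone.

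Translation factors, chaperones, proteasome subunits and genes for lysosomes and autophagy also held summits more often than other genes. Translation factors reached 11 of 40 members (Fisher's adjusted p = 2.74e-05), with iff-2 (113 ± 13.2, n = 2), eef-2 (113 ± 29.3), eif-3.C (103.8 ± 21.6) and eef-1A.1 (72.2 ± 16.04). Chaperones reached 14 of 59 (Fisher's adjusted p = 1.49e-05), with the chaperonin subunit genes cct-8 (145 ± 29.2) and cct-1 (85.0 ± 7.4), the DnaJ gene dnj-13 (127 ± 6.5) and the endoplasmic reticulum gene hsp-3 (121 ± 2.5). This call was lost when each summit was given to its nearest gene (Fisher's adjusted p = 0.117). Proteasome subunits reached 8 of 33 (Fisher's adjusted p = 0.000967), with rpn-3, rpn-9, pas-4 and rpt-6. This call was lost with circular shifts in place of Fisher's test (adjusted permutation p = 0.0597) and in the list of replicate 1 alone, with 6.06% of members (Fisher's adjusted p = 0.36). Genes for lysosomes and autophagy reached 13 of 53 (Fisher's adjusted p = 1.94e-05), led by epg-7, lgg-2, epg-8 and vha-12. In the replicates' own lists the share of lysosome and autophagy genes was 13.2% ± 2.67 and that of translation factors 18.75% ± 1.77 (SD, n = 2). With 250 bp windows the share of translation factors was 15%, of chaperones 10.2% and of lysosome and autophagy genes 15.1%. The shares among other genes were then 3.50%, 3.51% and 3.49%. Among the 1165 peaks of higher signal, the share of lysosome and autophagy genes was 9.43%, against 3.04% of other genes. With each summit given to its nearest gene, 42.4% of proteasome genes and 41.5% of lysosome and autophagy genes were reached. This assignment is not limited to the promoter window. It raised the shares among other genes from 5.65% to 9.55% and from 5.63% to 9.52%, so these shares do not describe promoter windows alone.

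Genes for splicing, respiration and chromatin also held summits more often than other genes. Of 71 nuclear genes for the respiratory chain and ATP synthase, 17 held a summit (Fisher's adjusted p = 1.71e-06), with cox-5B (164 ± 35.9, n = 2), cox-5A (150 ± 18.6), atp-1 (145 ± 6.9) and cyc-1 (59.9 ± 26.2). Splicing factors reached 14 of 44 (Fisher's adjusted p = 5.01e-07), with snr-4 (75.2 ± 0.8), the divergent neighbours rsp-1 and rsp-2 (74.9 ± 23.7 at their shared peak) and prp-8 (55.1 ± 12.2). The peak at snr-4 also overlaps the snRNA gene T11F9.15. Chromatin regulators reached 21 of 106 (Fisher's adjusted p = 1.94e-06), with the SET domain genes set-21 and set-16 (101.5 ± 13.8), lin-53, which encodes a histone-binding protein (111 ± 19.8), and lin-9 (98.0 ± 15.1). The peak at set-21 is shared with rpl-7A. In the replicates' own lists the shares were 13.4% ± 2.99 for respiration, 18.2% in both for splicing and 11.8% ± 0.67 for chromatin (SD, n = 2). With 250 bp windows they were 18.2% for splicing and 12.3% for chromatin, against 3.49% and 3.48% of other genes.

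Cell cycle and replication genes reached 11 of 78 (Fisher's adjusted p = 0.00962), with cdc-48.1, knl-3, rfc-4 and pcn-1, and 8.97% of them in either replicate's own list. The peak at rfc-4 is also that of eef-1A.1, and this call was lost with circular shifts (adjusted permutation p = 0.145). The list was matched by gene symbol alone, so its name is only a rough label for its members. Histone genes reached 9 of 72 (Fisher's adjusted p = 0.0406), with his-37, his-67, his-68 and his-59. These 9 genes had 7 promoter peaks between them, and neighbours such as his-67 and his-68 share a peak. The histone call was lost in the other list of the series (7 members, Fisher's adjusted p = 0.174) and in 5 further alternatives. Histone genes are also near-identical copies, so their peaks are uncertain. The share of histone genes was 8.33% and 5.56% in the lists of replicates 1 and 2, and 20.8% with windows from 1000 bp upstream. The shares among other genes were 3.00%, 3.04% and 6.73%.

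Large gene families of the nematode held few summits. Chemoreceptor genes had summits at 4 of 1308 members (odds ratio 0.0476, 95% interval 0.0129 to 0.123, Fisher's adjusted p = 2.1e-27), and immune effector and detoxification families at 4 of 497 (adjusted p = 9.95e-08 by the same test). F-box and related families had 5 of 395 (Fisher's adjusted p = 3.45e-05), a call lost with circular shifts (adjusted permutation p = 0.0803). In either replicate's own list 2 of the F-box and related genes (0.506%) and 2 of the immune and detoxification genes (0.402%) held a summit, as did 2 of the former in the other list of the series. Without peaks at tRNA, snoRNA or snRNA genes, 1 immune or detoxification gene (0.201%) held a summit. The count was also 1 among the 1165 peaks of higher signal and with 250 bp windows. With each summit given to its nearest gene the shares were 1.76% for chemoreceptors, 3.02% for immune and detoxification genes and 2.78% for F-box and related genes. Under this assignment, which is not limited to the promoter window, the shares among other genes were 10.2%, 9.77% and 9.74%. In the main setting they were 6.05%, 5.80% and 5.77%. Nuclear receptors had 7 of 269 (Fisher's adjusted p = 0.0439), a call lost in both replicates' own lists (adjusted p = 0.222 and 0.295), among the 1165 peaks of higher signal (0.235), without peaks at tRNA, snoRNA or snRNA genes (0.0977) and with windows from 1000 bp upstream (0.206). It was also lost with circular shifts (adjusted permutation p = 0.485) and turned direction with each summit given to its nearest gene (Fisher's adjusted p = 0.994).

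The remaining lists did not pass the threshold against other genes by Fisher's exact test with Benjamini-Hochberg adjustment. Members with a summit were 1 of 89 sperm genes (Fisher's adjusted p = 0.111), 5 of 183 neuronal genes (0.161), 4 of 32 aminoacyl-tRNA synthetases (0.161), 7 of 70 mitochondrial ribosome genes (0.171), 6 of 186 collagens and cuticle genes (0.273), 2 of 84 homeobox genes (0.295), 3 of 31 insulin and stress signalling genes (0.295), 1 of 59 cilium genes (0.295), 2 of 72 intestinal genes (0.467), 6 of 76 germline genes (0.467) and 1 of 46 muscle genes (0.52). Neuronal genes held summits less often than other genes in the list of replicate 1 (0 members, Fisher's adjusted p = 0.0175), among the 1165 peaks of higher signal (0.0178), with windows from 1000 bp upstream (0.0141) and against genes with a symbol (0.0369). Against genes with a symbol, sperm genes also did so (Fisher's adjusted p = 0.0381). Mitochondrial ribosome genes held summits more often with windows from 1000 bp upstream (Fisher's adjusted p = 0.0458). With each summit given to its nearest gene, insulin and stress signalling genes held them more often (9 members, Fisher's adjusted p = 0.00459) and cilium genes less often (0 members, Fisher's adjusted p = 0.0129). Among promoter peaks, the median percentile of signal was 66.6 for ribosomal protein genes and 79.0 for chaperones. Neither passed the permutation test against random draws (adjusted p = 0.0714 for both), nor did any of the other 12 lists tested.

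**Figure D3:**
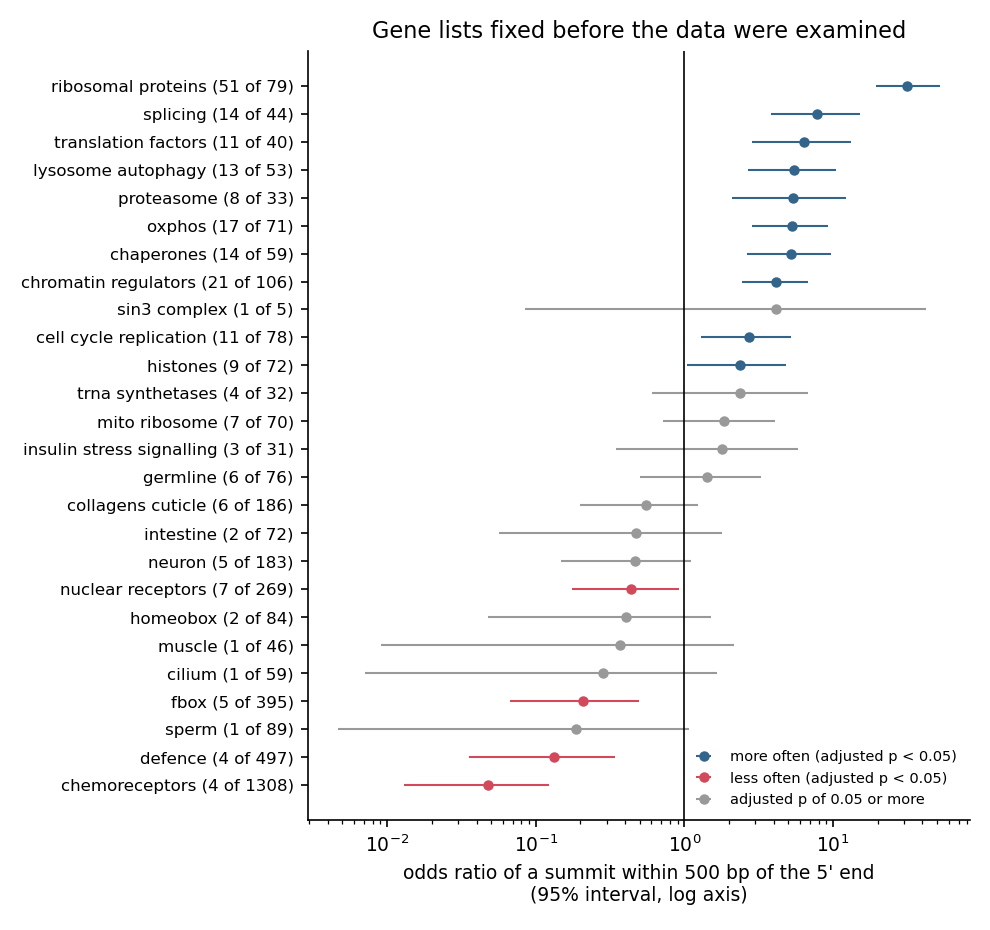
Odds ratio (x axis, log scale) of a summit within 500 bp of the 5' end for members of each list against all other protein-coding genes, with 95% intervals and, in brackets, members with a summit of all members. Blue lists held summits more often and red lists less often at an adjusted p under 0.05. Ribosomal proteins (51 of 79) and chemoreceptors (4 of 1308) lie at the ends.

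Genes for tRNAs and other small RNAs were among the most frequent sites. The conservative list had 361 peaks over tRNA genes, against 12.7 after shifts (28.4-fold). On the nuclear chromosomes alone, an alternative chosen after seeing the data, there were 352 against 4.45 (79.2-fold), and 367 of 612 nuclear tRNA genes (59.97%, exact 95% interval 56.0 to 63.9) overlapped a peak. Peaks over snoRNA genes numbered 79 (24.1-fold over shifts) and over snRNA genes 35 (33.3-fold), which reached 80 of 346 and 34 of 129 genes. For snoRNA genes the fold was 43.0 and 42.5 in the lists of replicates 1 and 2, and 39.7 among the 1165 peaks of higher signal. The replicates' own lists had 254 and 255 tRNA peaks, which were 20.5% ± 0.3 (SD, n = 2) of their peaks. The highest nuclear tRNA peak lay inside him-4 on the X chromosome (9743654 to 9743787), over the genes F15G9.t1 and F15G9.t2, with a signal of 125 ± 7.4 (n = 2). The highest over all chromosomes were the mitochondrial peaks at CYTB and ND5. Among snRNA genes the highest were sls-2.4 on chromosome I (4172059 to 4172468; 148 ± 12.6) and sls-2.1 on chromosome II (110 ± 36.7), which encode spliced leader RNA. Among snoRNA genes they were ZK994.7 and C51F7.3, the latter inside frm-7 (210 ± 3.9). Many tRNA genes are identical copies, so which copy a peak belongs to is uncertain.

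Peaks over other non-coding RNA genes numbered 455, against 65.5 after shifts, and 260 of them also overlapped a tRNA, snoRNA or snRNA gene. Without peaks at those genes the fold fell from 6.95 to 3.90. Of the 455, 128 also lay in a promoter window of a protein-coding gene, and the fold without these was not computed. The highest of the 455 was at rpr-1, the RNA subunit gene of RNase P, inside ints-8 on chromosome I (13463843 to 13464066, 185 ± 7.2). The next was at F56F3.10 beside rps-1 (183 ± 0.07) and is the same peak as that of the rps-1 promoter. Pseudogenes were overlapped by fewer peaks (27) than after shifts (78.8). The highest of these, at 6212827 to 6212904 on chromosome I inside fars-1 and at 8927150 to 8927419 on chromosome IV inside cfim-2, had signals of 92.2 ± 7.5 and 82.2 ± 11.3 (n = 2). The adjusted permutation p was 0.0014 for each of these 5 classes, from the smallest p that 1000 shifts can give. Genes for rRNA (5 peaks, adjusted permutation p = 1) and miRNA (5 peaks, adjusted p = 0.0629) did not pass the test. Genes for miRNA passed in the other list of the series (7 peaks, 3.59-fold, adjusted permutation p = 0.00816), in the lists of replicates 1 and 2 (3.96-fold and 4.04-fold, adjusted permutation p = 0.0361 and 0.035) and without peaks at tRNA, snoRNA or snRNA genes (3.23-fold, adjusted permutation p = 0.042). Genes for rRNA passed with the 95 further ranked peaks added (8 peaks, adjusted permutation p = 0.0303).

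**Figure D4:**
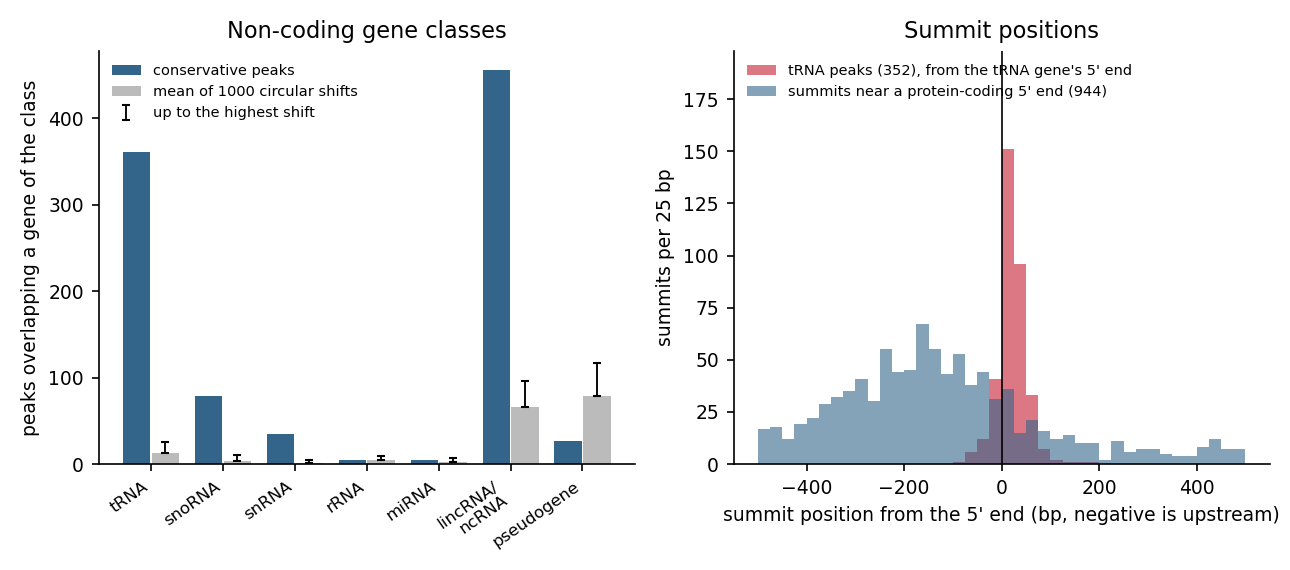
Left, peaks overlapping a gene of each non-coding class (y axis, count) for the conservative list (blue) and the mean of 1000 circular shifts (grey, whiskers up to the highest shift). Right, number of summits per 25 bp (y axis) by position from the 5' end (x axis, bp), for 352 nuclear tRNA peaks (red) and 944 nuclear summits near a protein-coding 5' end (blue). tRNA summits sit at the gene's 5' end, and protein-coding summits centre upstream.

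Peaks were spread over all chromosomes, from 15.2 per Mb on chromosome V to 34.7 on chromosome III among the nuclear chromosomes. The X chromosome held 357 of 2306 nuclear peaks (15.5%, exact 95% interval 14.03 to 17.02). This was under its 17.7% of the sequence (adjusted p = 0.0107, exact binomial test) and over its 13.7% of protein-coding 5' ends (adjusted p = 0.0172), a call lost in the other list of the series (15.2%, adjusted p = 0.0552, exact binomial tests). Without peaks at tRNA, snoRNA or snRNA genes, an alternative chosen after seeing the data, 10.8% of peaks lay on X, under its share of 5' ends (adjusted p = 0.000372, exact binomial test). In the replicates' own lists the share was 18.5% ± 0.4 (SD, n = 2), which did not pass against its share of sequence (adjusted p = 0.818 and 0.295, exact binomial tests). The middle 33.3% of the autosomes by length held 39.0% of autosomal peaks (adjusted p = 5.51e-07), close to its 38.1% of 5' ends (adjusted p = 0.401, exact binomial tests).

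Promoter peaks and other peaks had similar signal, with a median of 78.7 at 959 promoter peaks and 75.3 at 1371 others. The log2 difference of 0.06 did not pass the permutation test (p = 0.0555, 2-sided), and among the 1165 peaks of higher signal it was -0.01 (permutation p = 0.566). Without peaks at tRNA, snoRNA or snRNA genes it was 0.12 (permutation p = 1e-05, the smallest that 100000 resamples can give). Median signal was 99.1 at 466 nuclear peaks over these small RNA genes, 75.5 at 862 promoter peaks without them and 69.3 at 978 peaks with neither.

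Sequence at summits was richer in G and C than its surroundings and held particular short words. The GC share around 2327 summits was 44.1% ± 7.4 (SD across windows), against 37.2% ± 5.6 in windows 1000 bp away, and was higher at 1791 summits (permutation p = 1e-05, the smallest that 100000 resamples can give). The difference was 7.63 percentage points ± 0.05 (SD, n = 2) in the replicates' own lists. Of 7 fixed motifs, GAGAGA was present in 29.9% of summit windows and 12.03% of flank windows (Fisher's adjusted p = 4.49e-70) and GCGCGC in 10.2% and 1.5% (adjusted p = 2.86e-58). TTCCCGC (3.27% and 2.19%, Fisher's adjusted p = 0.0114) and CACGTG (5.54% and 4.02%, adjusted p = 0.00684) were also more frequent, and TGATAA (12.5% and 18.01%, adjusted p = 5.37e-09) and AATTAATT (1.33% and 3.03%, adjusted p = 1.42e-05) less frequent. TTCCCGC did not pass in the lists of replicates 1 and 2 (Fisher's adjusted p = 0.229 and 0.189), nor CACGTG in the other list of the series (0.102) or among the 1165 peaks of higher signal (0.181). TGACGTCA did not pass (Fisher's adjusted p = 0.448). Against windows matched on GC, an alternative chosen after seeing the data, GAGAGA and GCGCGC passed (Fisher's adjusted p = 3.7e-45 and 4.37e-35) and the other motifs did not.

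Among 2080 6-mers, 747 were more and 591 less frequent at summits than in flanks. Ranked by p-value, the leading word was ACGCAG, with its reverse complement CTGCGT. It was in 19.8% of summit windows and 4.32% of flank windows (odds ratio 5.47, adjusted p = 1.61e-86 by Fisher's exact test). GAGAGA, AGACGC and AGAGAC came next, with odds ratios of 3.11, 4.53 and 3.62. CGAACC, in 15.9% and 4.19% of windows, had an odds ratio of 4.34, and GCGCGC one of 7.46. Without peaks at tRNA, snoRNA or snRNA genes, CGAACC was no longer among the leading words, while ACGCAG, GAGAGA, AGACGC and AGAGAC were. The words that stayed overlap each other and are not independent.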

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

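The comparisons made from this list were chosen after the result was seen. The ranked list of the series, which the main comparisons do not use and from which 1 alternative adds peaks, holds 2425 peaks at or past the IDR threshold, and 95 of them are absent from the conservative list. They stand out as signal in a list outside the main measurement. Their median signal is 108, against 76.5 in the conservative list, and they make up 13 of the 50 nuclear peaks of highest signal past the threshold. The highest, at 15810948 to 15811180 on the X chromosome, has a signal of 2500, above every nuclear peak of the conservative list, and 1213 and 1467 in the replicates' ranked lists. It lies 6938 bp from the nearest protein-coding 5' end, that of Y7A5A.7. Of the 95, 92 have a ranked peak in both replicates, 88 lie in intergenic sequence, 1 lies in a promoter window and 0 overlap a tRNA, snoRNA or snRNA gene. Per the deposited file notes, the thresholded lists were derived from 1 further file that the ranked lists were not. What that file holds is not given in the sources used here, and no explanation was tested.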

How the results depend on the processing

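Alternatives on the nuclear chromosomes alone, without peaks at tRNA, snoRNA or snRNA genes, with the 95 ranked peaks added, and with windows matched on GC were chosen after seeing the data. Of 134 recomputed main values, 122 kept their direction and their side of the threshold, or their count within 1.5 times. The promoter share ran from 27.04% with 250 bp windows to 47.0% and the GC difference from 6.10 to 10.3 percentage points, and the overlap of replicates from 59.3% to 69.8% and from 57.9% to 68.3%. Using each replicate's own list, the X share was 18.2% to 18.8%, and with the 1165 peaks of higher signal 19.2%, so that it no longer lay under the share of sequence; the cause was not tested. Against 5' ends, the X share was 15.2% in the other list of the series (adjusted p = 0.0552, exact binomial test), and 10.8%, the opposite direction, without peaks at tRNA, snoRNA or snRNA genes. That same set left 2 non-coding classes over shifts and 0 peaks at tRNA, snoRNA and snRNA genes, by its construction, and raised the log2 signal difference of promoters to 0.12. Among the 1165 peaks of higher signal this difference was -0.0122; the cause was not tested. With circular shifts, 2 lists held summits less often. With 250 bp windows intergenic sequence held 29.2% of summits, above the 28.2% after shifts and not past the threshold; the cause was not tested. With each summit given to its nearest gene, 9.67% of nuclear receptors were reached, above the 9.60% of other genes and not past the threshold. The cause was not tested. Against windows matched on GC, 2 motifs were more and 0 less frequent, 453 6-mers were more frequent, and CACGTG (5.54% of summit windows) and TGATAA (12.5%) turned direction without passing. Values that passed neither before nor after also turned direction: the 5' UTR share with 5' ends of every transcript (0.215%), the 3' UTR share (1.80%) and TGACGTCA (0.775%) among the 1165 peaks of higher signal, TGACGTCA against windows matched on GC (1.17%) and in the replicates' own lists (0.637% to 1.14%, turned in that of replicate 2), cilium genes in the replicates' own lists (1.69% to 3.39%, turned in that of replicate 1), SIN-3 complex genes (0%) and neuronal genes (9.84%) with each summit given to its nearest gene, and rRNA genes (5 peaks in both replicates' own lists, turned in that of replicate 1, and 0 on the nuclear chromosomes). The cause was not tested. Of 953 other values, 875 were the same, 26 lost their call, 15 gained one, 17 turned direction and 20, named genes without a summit, moved. Of 62 named genes with a summit, 61 kept it in the list of replicate 2 alone and 57 in that of replicate 1 alone. The depth of the libraries is unknown, so absence of a peak is not absence of binding.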

Other observations

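The tests of identical tRNA copies, of promoters beside tRNA genes, of X without small RNA genes, of ACGCAG without small RNA genes and of operon-like genes were fixed before their results were seen, and the other tests in this part were chosen after. Peaks reached tRNA genes of each standard amino acid. Shares ran from 27 of 34 alanine genes (79.4%), 10 of 13 cysteine genes (76.9%) and 20 of 27 aspartate genes (74.1%) to 15 of 39 serine genes (38.5%) and 4 of 12 tryptophan genes (33.3%). Summits at nuclear tRNA genes lay a median of 19 bp into the gene from its 5' end, and 98.6% lay within 100 bp of it. Along the nuclear ranked list, small RNA genes were at 33% of the first 500 peaks, 28% of the next up to rank 1000, 12.9% from there to rank 2000 and 4.35% from there to rank 4000. Promoters were at 38.4%, 39.8%, 41.2% and 31.5% of the same peaks, and at 18.5% of the peaks from rank 32001 on.

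Divergent genes, which have another gene's 5' end on the opposite strand within 1000 bp, held a summit in 7.60% of 3539 cases against 3.94% of other genes when each summit was given to its nearest 5' end only (odds ratio 2.01, 95% interval 1.73 to 2.33). Genes whose 5' end lies within 500 bp downstream of a same-strand neighbour, as downstream members of an operon do, were counted with every summit in their window. They held a summit in 6.53% of 3615 cases against 5.49% of others (odds ratio 1.20, interval 1.04 to 1.39, Fisher's exact p = 0.0171). The idea that such genes hold summits less often is not borne out by this count. It differs from the count for divergent genes and includes summits nearer to another gene's 5' end. Annotated neighbours are a stand-in for operons, which were not analysed here.

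Peaks at tRNA genes were 361 of the 2330. Of 140 tRNA genes whose sequence occurs once, 60 held a peak (42.9%, interval 34.5 to 51.5). This was above the bound of 10% set for reads shared between identical copies as the cause. Genes with identical copies held a peak more often (65.0%, Fisher's exact p = 3.48e-06). A gene without an identical copy may still share reads with near-identical ones or lie under a neighbour's peak, so shared reads were not excluded. Neighbouring protein-coding promoters cannot be the whole account, since 15.9% of nuclear tRNA peaks lay in a promoter window (interval 12.2 to 20.2). Signal that any tagged protein, or untagged worms, might give at highly transcribed genes stays open, because values of a control library were not used here, and no biological explanation was tested with a single group.

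The share of peaks on X above that of 5' ends may come from small RNA genes on X. Of 612 nuclear tRNA genes, 276 lie on X, as do 156 of the 352 nuclear tRNA peaks, and without peaks at tRNA, snoRNA or snRNA genes 10.8% of peaks lay on X (interval 9.43 to 12.3), under the 13.7% of 5' ends. On X, 58.0% of tRNA genes held a peak, and on the autosomes 61.6% (Fisher's exact p = 0.363). A biological difference of X was not tested.

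The 6-mer ACGCAG is not explained by the sequence of small RNA genes alone, since its odds ratio without their peaks was 5.95 (95% interval 4.90 to 7.21). Higher GC at summits did not account for all of it either. Against neighbouring windows matched on GC (43.3% against 44.2% at summits) its odds ratio fell from 5.47 to 3.58 (interval 3.06 to 4.18), and 390 of the 747 6-mers stayed more frequent. Words shared by the promoters of particular gene groups remain a candidate explanation that was not tested, and so does a bias that a control library would show.

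The conservative list also holds 45 peaks with a signal under 20 (median 8.09), of which 37 have a ranked peak in both replicates. The median signal of the overlapping ranked peaks is 31.3 in replicate 1 and 34.1 in replicate 2.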
